A study of Mus musculus with 12 samples.

How the data were processed

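The series compared colon tissue from normally fed C57BL/6J mice with colon tissue from mice given 2,4,6-trinitrobenzenesulfonic acid (TNBS), a hapten instilled into the colon to provoke colitis. Per the labels' protocols, the mice were male, 6 to 8 weeks old and 20 to 22 g, and the TNBS solution was 5% w/v. Each mouse gave an RNA library immunoprecipitated with an antibody against N6-methyladenosine (m6A) and an input library, 12 libraries from 6 mice in all. The group and the mouse number were taken from the sample labels. The extraction protocol in the labels speaks of retinas, while the tissue, source and title fields say colon, so a list of retina markers was included among the gene lists.

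The authors deposited 1 list of m6A peaks per mouse, limited to peaks in mRNA transcripts and made by setting the immunoprecipitated library against its input. The peaks carry the numbering of the caller MACS, per the file headers and peak names, and were called in each mouse separately. Per the submitters' processing notes, base calling used CASAVA 1.8 and alignment used BWA, with hg19 named as the genome build. That build is human. The listed positions overlapped the mouse gene of the same gene identifier in the GRCm38 gene table for 99.1% to 99.5% of the peaks whose identifier was in that table, so positions are given as the files list them, in mouse coordinates, counted from 1. Aligner settings, the caller's version and settings, and read depths were not given in the sources used here, so the depth behind each peak is unknown.

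Each peak has a score, minus 10 times the log10 of the caller's p-value, as the authors deposited it. The lowest score in any list was 50, which is a p of 1e-05. Each peak also has a fold enrichment, the ratio of immunoprecipitated to input signal as the authors deposited it, and a false discovery rate in percent, per the file headers. These values are the authors' own values for each peak. The score and the fold enrichment were used to describe, rank or filter peaks within 1 list, and neither was tested between mice. The share of peaks at a false discovery rate of 100% was compared between groups. Some cells of a gene ontology column were emptied before this work, and that column was not used here.

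From the lists, the peaks and the distinct gene symbols were counted per library. A gene or region was compared between groups by presence of a listed peak, and regions were made by merging peaks of the 6 lists that shared at least 1 base. Genes and regions with a peak in 3 of 3 libraries of a group and 0 of 3 of the other are called restricted to that group. Group means were compared with exact two-sided permutation tests over all regroupings of 3 against 3, whose smallest p is 0.1, so no single gene can pass a threshold of 0.05. Counts of restricted genes and regions were set against the other splits among the 10 possible splits of the 6 libraries. Similarity of peak sets was the Jaccard index, the bases shared divided by the bases covered by either list.

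The 25 gene lists, 613 entries in all, were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, except where the text says otherwise. The 23 lists with at least 5 members that had a peak in any library were tested with two-sided Fisher's exact tests for membership among the genes restricted to each group, against the 11548 genes with a peak in any library, with Benjamini-Hochberg adjustment over 46 tests. Beside this, the share of a list's members with a peak, minus the share of all genes, was compared between groups with the exact permutation test, and each list's mean difference was ranked among 10000 random lists matched on the number of libraries with a peak. The symbol Virma was matched through its gene identifier to 1110037F02Rik, the symbol in the files.

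Genes named in the text were chosen by a rule. In each direction it took the 10 restricted genes whose strongest peak (smallest caller's p) had the highest mean percentile within its own list, leaving out clone and model names. It also took every member of the m6A writer, eraser and reader lists with a peak, up to 4 members of each other list with the largest difference between groups in the number of libraries with a peak, and the 3 genes with a peak in all 6 libraries and the highest mean percentile. Some genes that this rule takes are not reported here. Other genes are said to have been chosen after their values were seen.

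The alternatives were a caller's p of 1e-10 or less, a fold enrichment of at least 4, the same number of peaks (10971) from each list, leaving out each library, other definitions of a restricted gene, gene assignment by overlap with GRCm38 protein-coding genes, overlap of at least 50% of the shorter peak, a narrower background and pairing by replicate number. The location of peaks along transcripts and the sequence motif at peaks were not analysed here. On simulated presence data for the 11548 genes with 200 genes restricted to 1 group, the counting step found 80.5% of them where 80.7% was the value set by the simulation, and it also called 45 genes that had not been set so. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.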

Results

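Transcripts carrying m6A, the commonest internal modification of mRNA, were mapped by antibody pull-down and sequencing in colon from 3 normal mice and from 3 mice with TNBS colitis, a model of Crohn's disease. The series title names FTO, an enzyme that removes m6A, and the comparison asks which transcripts carried m6A peaks in inflamed and in normal colon. The normal lists held 16488, 16324 and 13992 peaks and the TNBS lists 18752, 10971 and 19285 peaks. Each list came from 1 mouse label, and the exact permutation p-values measure the spread between these 6 labelled samples. Fisher's exact tests take genes as units, so their p-values describe the lists of genes and not that spread. Peak presence depends on transcript abundance and read depth as well as on m6A, and neither was measured separately here.

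The transcripts of both m6A erasers, Fto and Alkbh5, had a peak in 6 of 6 libraries. In Fto the peak at chromosome 8, 91409223 to 91409841, was listed in every library, and in Alkbh5 the peak at chromosome 11, 60537683 to 60539195. Of the 12 genes of the m6A writer list, 11 had a peak in any library and 8 had one in all 6, among them Wtap, Rbm15, Rbm15b, Zc3h13, Cbll1 and Virma (listed as 1110037F02Rik), which belong to the complex that places m6A. Mettl14, a core subunit of that complex, had a peak in TNBS 1 alone, at percentile 1.74 of that list. Mettl16 had a peak in 1 normal and 2 TNBS libraries and Zcchc4 in 2 normal and 1 TNBS library. The Mettl16 peak in TNBS 3 stood at percentile 0.762. Among the m6A readers 8 of 12 had a peak, and Ythdf1, Ythdf2, Ythdf3, Ythdc1, Igf2bp2, Fmr1 and Prrc2a had one in all 6 libraries, while Ythdc2 had one in 2 normal and 2 TNBS libraries. The Ythdc2 peak in TNBS 1 stood at percentile 0.619. The writer list had 9 ± 1 members with a peak per normal library and 9.33 ± 0.577 per TNBS library (mean ± SD, n = 3 each, exact permutation p = 0.7), and the reader list 7.67 ± 0.577 in both groups (exact permutation p = 0.8), where p compares shares relative to all genes.

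The number of peaks differed between colitis and normal colon by less than the spread between mice. TNBS libraries held 16336 ± 4654 peaks and normal libraries 15601 ± 1396 (mean ± SD, n = 3 each, two-sided exact permutation p = 1). Genes with a peak numbered 8619 ± 1503 in TNBS and 8688 ± 468 in normal libraries (n = 3 each, exact permutation p = 1). A peak was present in all 6 libraries in 5554 of 11548 genes. The highest of these, by rank of the caller's p within their lists, were Myh11, the myosin heavy chain of smooth muscle, and Plekha7 and Camsap3, which encode proteins of epithelial junctions and of microtubule minus ends. From 8.65% (TNBS 2) to 18.8% (normal 1) of a list's peaks scored 3100 or more, with many ties. Rbm15, Ythdc1 and Zc3h13, among others, tied at a mean percentile of 92.3, against 95.4 for Myh11. The order at the top therefore sets these genes little apart, and ranks of restricted genes share this limit. TNBS 2 stood apart with 6884 genes. Without it the difference in peaks (TNBS minus normal) was 3417 in place of 735, and without normal 3, TNBS 1 or TNBS 3 it was -70.0, -473.3 or -739.8. The difference in genes was 798.5 without TNBS 2, 105 without normal 1 and 23 without normal 2, where it had been -69.0. No peak in any list had a caller's false discovery rate of 5% or less, and the share of peaks at a rate of 100% was 10.5%, 13.7% and 37.8% in normal lists and 66.6%, 100% and 99.99% in TNBS lists (exact permutation p = 0.1, n = 3 each, the smallest possible).

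**Figure D1:**
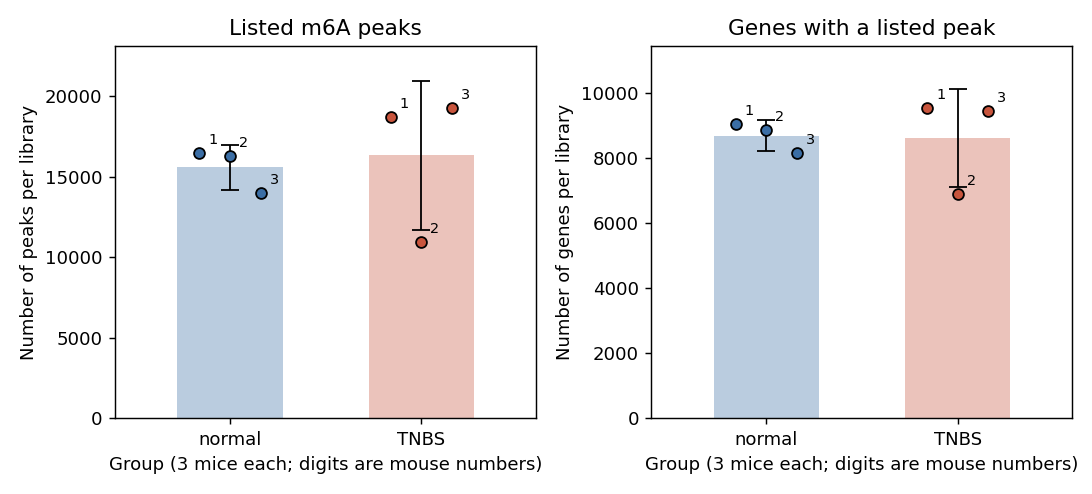
Number of listed m6A peaks (left) and of genes with a listed peak (right) per library, with bars for group means, error bars for the SD (n = 3 mice per group) and points for single mice. The TNBS points run from 10971 to 19285 peaks and span the range of the normal points, 13992 to 16488.

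Genes with a peak in every TNBS library and no normal library numbered 115. By the rank of their strongest peak the first 10 were Tor2a, Rps9, Hist1h2ad, Rab11b, Angptl4, Hrc, Rasgrp4, Krt7, Eif5a and Adamts4. Angptl4, a secreted inhibitor of lipoprotein lipase, had a peak ending at 33775568 on chromosome 17 in each TNBS list, with a fold enrichment of 10.4, 16.7 and 28.3. Krt7, a keratin of simple epithelia, had its strongest peak at a fold enrichment of 19.1, 8.58 and 12.0. Adamts4, a protease of cartilage and matrix proteoglycans, reached 37.8, 20.7 and 12.3, and Rasgrp4, a Ras activator of mast cells, 15.6, 6.80 and 42.4. Rab11b, a GTPase of recycling endosomes, reached 9.91, 8.55 and 14.1, and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, 6.84, 12.3 and 19.8. Rps9, a protein of the small ribosomal subunit, had a peak ending at 3706897 on chromosome 7 in each TNBS list, with a fold enrichment of 18.6, 6.94 and 22.1. The translation factor Eif5a had the peak at chromosome 11, 69916712 to 69917341, in each TNBS list, with 12.53, 7.20 and 9.45. Rps9, Eif5a and Hist1h2ad belong to families with near-identical copies or pseudogenes, so their assignment is uncertain. Tor2a and Hist1h2ad overlapped peaks that all 3 normal lists gave to the neighbouring genes Ttc16 and Hist1h3d, so for both genes the name attached to overlapping peaks differed between groups.

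Genes with a peak in every normal library and no TNBS library numbered 120. The first 10 were Morf4l2, Ttc16, Capn13, Rpl4, Cd24a, Frrs1, Zfp738, Tmem132a, Yipf5 and Polr3k. Cd24a, a glycoprotein anchored at the cell surface, had the peak at chromosome 10, 43582604 to 43584265, in each normal list, with a fold enrichment of 9.90, 9.45 and 6.81. Capn13, a calpain protease, had the peak at chromosome 17, 73322025 to 73322100, with 45.1, 33.2 and 25.1. Rpl4, of the large ribosomal subunit, had the peak at chromosome 9, 64178223 to 64178562, with 13.9, 12.0 and 10.2. Frrs1, a ferric reductase, had the peak at chromosome 3, 116903069 to 116903750, with 22.1, 20.5 and 16.6, and Polr3k, a subunit of RNA polymerase III, the peak at chromosome 2, 181864337 to 181864569, with 17.4, 18.6 and 10.9. Morf4l2, a chromatin protein on the X chromosome, reached 13.5, 11.7 and 10.2, the zinc finger gene Zfp738 8.17, 6.64 and 6.01, and Yipf5, a Golgi protein, 13.7, 11 and 8.84. Rpl4 and Morf4l2 have processed copies in the genome and their assignment is uncertain. Ttc16 and Tmem132a overlapped peaks that all 3 TNBS lists gave to Tor2a and Slc15a3. In all, 5 of the 235 restricted genes overlapped a peak of the other group under another name.

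In both directions 235 genes followed the groups, and the highest count for any other split of the 6 libraries was 121. With 10 splits the smallest share that the real one can reach is 0.1. Taken 1 trio of libraries at a time, normal 1 with TNBS 1 and TNBS 3 shared 117 genes that no other library had, more than the 115 of the TNBS trio, and the median of the 18 mixed trios was 15.5. TNBS 1 and TNBS 3 listed no peak in the male-specific part of the Y chromosome, whereas each normal library listed 12 and TNBS 2 listed 19. Leaving out a library loosens the rule, so both restricted counts could only hold or rise, and a rise by itself does not show dependence on that library. The TNBS count ran from 151 to 537 genes over the libraries left out, the highest without TNBS 2 and the next, 178, without TNBS 1. The normal count ran from 145 to 347 genes, the highest without TNBS 1. Of the 115 and 120 genes, 40 and 67 stayed restricted at a caller's p of 1e-10 or less, and 45 and 44 with the same number of peaks from each list, where 137 and 210 genes were restricted.

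**Figure D2:**
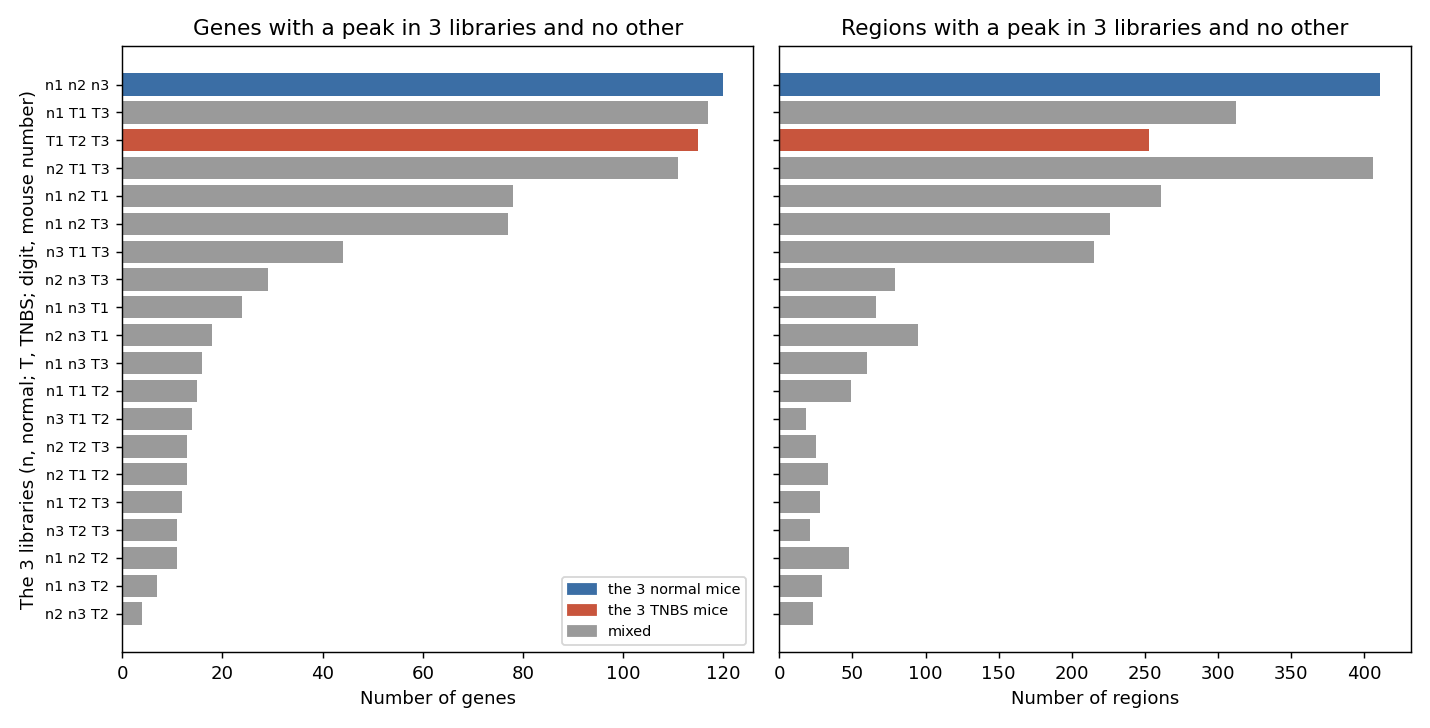
Number of genes (left) and of merged regions (right) with a peak in exactly the 3 libraries named on the vertical axis (n, normal; T, TNBS; digit, mouse number). The normal trio holds 120 genes and 411 regions and the TNBS trio 115 genes and 253 regions; the highest mixed trios hold 117 genes and 406 regions.

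At the level of single peaks, 26654 merged regions were found and 7569 were called in all 6 libraries. Regions called in every TNBS and no normal library numbered 253, and 118 of them lay in genes that had a peak in all 6 libraries. Regions called in every normal and no TNBS library numbered 411, and 177 of them lay in such genes. Genes restricted in the same direction held 93 of the 253 and 117 of the 411. The 664 regions of both directions compare with 435 for the highest other split of 10. The trio of normal 2, TNBS 1 and TNBS 3 held 406 regions. Leaving out a library, which loosens the rule, gave 316 to 2102 TNBS regions, the highest without TNBS 2. It gave 475 to 930 normal regions, the highest without normal 3.

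Peak sets overlapped more among normal than among TNBS libraries, a difference that was not itself tested. The mean Jaccard index was 0.765 over pairs of normal libraries and 0.590 over pairs of TNBS libraries, where the pair of TNBS 1 and TNBS 3 had 0.739 and both pairs with TNBS 2 had 0.517 and 0.514. Within groups the mean was 0.677 over 6 pairs, and between groups 0.635 over 9 pairs. The difference of 0.0425 was the highest of the 10 splits (exact share 0.1, the smallest possible), and the highest other split gave 0.0130. The difference was -0.00421 without normal 1, -0.00485 without normal 2 and 0.00555 without normal 3, so its direction was not stable. Leaving out a normal library removes normal pairs, so the low pairs with TNBS 2 weigh more in the mean within groups. The difference was 0.0994 without TNBS 1, 0.0749 without TNBS 2 and 0.0840 without TNBS 3.

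Among transcripts of inflammation, cytokines and chemokines carried peaks in more TNBS than normal libraries. Of 32 listed genes 14 had a peak in any library, and 4.33 ± 1.53 did so per normal library against 9.33 ± 3.21 per TNBS library (mean ± SD, n = 3 each, exact permutation p = 0.1, the smallest possible). For this list and those below, the p compares the share of members with a peak minus the share of all genes. Counts were 6, 4 and 3 in the normal and 13, 7 and 8 in the TNBS libraries, of which TNBS 1 and TNBS 3 are those without listed peaks in the male-specific part of the Y chromosome. Ccl5, a chemokine for T cells, had the peak at chromosome 11, 83525778 to 83526064, in 3 of 3 TNBS and 0 of 3 normal libraries. This peak stood at percentile 2.28 of its list in TNBS 1, and Ccl5 was no longer in 3 of 3 at a caller's p of 1e-10 or less or with the same number of peaks from each list. Tnf had one in 3 TNBS and 1 normal library, and Cxcl9 and Cxcl12 each had one in TNBS 1 and TNBS 3 alone. In all, 10 of the 14 had a peak in more TNBS than normal libraries and 0 in fewer. The neutrophil list had a peak in 5 of 20 genes, with 0.333 ± 0.577 per normal and 2 ± 2 per TNBS library (exact permutation p = 0.4, n = 3 each). S100a9, a calcium-binding protein abundant in neutrophils, had one in TNBS 1 and TNBS 2, and Csf3r, Fpr1 and Ly6g each had one in a single TNBS library. NF-kB and TNF signalling genes were level at 28.3 ± 2.08 and 28.3 ± 3.06 of 33 (exact permutation p = 0.9, n = 3 each). Within that list the adaptor Myd88 had a peak in 1 normal and 3 TNBS libraries, Nlrp3 in 0 and 2, and the inhibitor Nfkbia and the adhesion molecule Vcam1 in 3 and 1. JAK-STAT and interferon genes stood at 18.7 ± 0.577 and 19.3 ± 5.51 of 24 (exact permutation p = 0.6, n = 3 each), with Stat3, Jak3 and Gbp2 in 0 normal and 2 TNBS libraries and Jak2 in 3 and 1. Monocyte and macrophage markers stood at 12.7 ± 0.577 and 10.3 ± 4.62 of 14 (exact permutation p = 0.1, n = 3 each, the smallest possible). Counts were 13, 13 and 12 in the normal and 13, 5 and 13 in the TNBS libraries, so the deficit in counts lay in TNBS 2 alone. Relative to all genes, the measure of the p, all 3 TNBS libraries lay below all 3 normal ones, TNBS 2 by the most. The 4 named members of this list, Cx3cr1, Fcgr1, Lyz2 and Mrc1, lacked a peak in TNBS 2 alone. Lymphocyte markers stood at 9.67 ± 2.52 and 8.33 ± 4.51 of 15 (exact permutation p = 0.6, n = 3 each), with the leukocyte antigen Ptprc in 2 normal and 0 TNBS libraries. The Ptprc peaks stood at percentile 2.58 in normal 1 and 23.3 in normal 2.

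In the epithelium, junction genes carried peaks in 20.3 ± 1.53 of 27 members per normal and 23.3 ± 4.04 per TNBS library (exact permutation p = 0.1 relative to all genes, n = 3 each, the smallest possible). Counts were 20, 22 and 19 in the normal and 24, 19 and 27 in the TNBS libraries. The rise in counts came from TNBS 1 and TNBS 3 alone, as for the ribosomal list below. Relative to all genes, the measure of the p, all 3 TNBS libraries lay above all 3 normal ones. Tjp3, a scaffold of tight junctions, had the peak at chromosome 10, 81291048 to 81291267, in 3 of 3 TNBS and 0 of 3 normal libraries, though Tjp3 was no longer in 3 of 3 with the same number of peaks from each list. The desmosomal cadherin Dsc2 had one in 1 normal and 3 TNBS libraries. Cldn2 and F11r had one in all but TNBS 2. Absorptive and transport genes stood at 22 ± 1 and 21.3 ± 5.69 of 27 (exact permutation p = 0.8, n = 3 each), with 23, 15 and 26 in the TNBS libraries. In that list the water channel Aqp4, the carbonic anhydrase Car2 and the fatty acid carrier Fabp2 had a peak in 3 normal and 1 TNBS library, and Car4 in 0 and 2. Goblet, Paneth, tuft and enteroendocrine markers stood at 8 ± 2 and 9 ± 2.65 of 15 (exact permutation p = 0.6, n = 3 each). The mucus proteins Fcgbp and Tff3 had a peak in TNBS 1 and TNBS 3, the antimicrobial lectin Reg3b in TNBS 2 and TNBS 3, and Muc1 in 3 normal and 1 TNBS library. Stem cell and Wnt genes stood at 23.3 ± 1.15 and 21.3 ± 4.04 of 26 (exact permutation p = 0.2, n = 3 each), with 25, 17 and 22 in the TNBS libraries, and with the stem cell factor Ascl2 and the ligand Wnt2b in 3 normal and 1 TNBS library, Axin2 in 3 and 2, and Ctnnb1 in 0 and 2. Cell cycle genes stood at 16 ± 1 and 12.3 ± 6.35 of 20 (exact permutation p = 0.3, n = 3 each). Birc5, Bub1b and E2f1 had a peak in 3 normal and 1 TNBS library and Plk1 in 3 and 2. TNBS 2, the shortest list, had 5 of these 20 genes and the other 5 libraries 15 to 17.

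Among stromal lists, extracellular matrix genes stood at 22.7 ± 0.577 in normal and 20.7 ± 9.29 in TNBS libraries, of 27 (exact permutation p = 0.9, n = 3 each). The single TNBS counts were 27, 10 and 25. The collagens Col3a1 and Col5a2 had a peak in TNBS 1 and TNBS 3 alone, and Col6a3 in all but TNBS 2. Smooth muscle markers stood at 16.7 ± 1.15 and 17.3 ± 1.15 of 19 (exact permutation p = 0.5, n = 3 each), with Acta2 in 0 normal and 2 TNBS libraries, Cnn1 in 1 and 2 and Kcnmb1 in 3 and 2. Endothelial and pericyte markers stood at 14.3 ± 0.577 and 15.3 ± 0.577 of 16 (exact permutation p = 0.4, n = 3 each), with Sox17 and Notch3 in 1 normal and 3 TNBS libraries, Lyve1 in 3 and 2, and Cdh5 in all 6. Enteric neuron and glia markers stood at 10.3 ± 2.52 and 11 ± 2 of 17 (exact permutation p = 0.7, n = 3 each), with Erbb3 in 2 and 3, Gal in 0 and 2, and Stmn2 in TNBS 3 alone. Adipocyte markers stood at 9 ± 1.73 and 10 ± 2.65 of 13 (exact permutation p = 0.5, n = 3 each), with Adipoq in 3 normal and 1 TNBS library, Fabp4 in 0 and 2, Cfd in 1 and 2, and Pck1 in TNBS 3 alone. Of 25 retina markers Abca4 alone had a peak, in TNBS 2.

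Among stress and housekeeping lists, ribosomal protein genes had a peak in 2.67 ± 0.577 of 9 members per normal and 5.67 ± 2.31 per TNBS library (exact permutation p = 0.1 relative to all genes, n = 3 each, the smallest possible). Counts were 2, 3 and 3 in the normal and 7, 3 and 7 in the TNBS libraries. The excess in counts lay in TNBS 1 and TNBS 3, those without listed peaks in the male-specific part of the Y chromosome. TNBS 2 was at the normal level in counts. Relative to all genes, the measure of the p, all 3 TNBS libraries lay above all 3 normal ones. Rplp1 and Rps9 had a peak in 3 of 3 TNBS and 0 of 3 normal libraries, and Rplp0 in 2 TNBS libraries. Rpl4 had one in 3 of 3 normal and 0 of 3 TNBS libraries. Rplp1 was no longer in 3 of 3 at a caller's p of 1e-10 or less. Hypoxia and glycolysis genes stood at 13.7 ± 0.577 and 15.3 ± 1.53 of 19 (exact permutation p = 0.3, n = 3 each), with the stress gene Ndrg1 in 0 normal and 2 TNBS libraries, Car12 in 2 and 3, and Car9 and Bnip3 in a single TNBS library each. Oxidative stress genes stood at 11 ± 1.73 and 12.3 ± 2.89 of 17 (exact permutation p = 0.2, n = 3 each). The mitochondrial superoxide dismutase Sod2 had a peak in 0 normal and 2 TNBS libraries, the amino acid transporter subunit Slc3a2 in 2 and 3, the transferrin receptor Tfrc in 3 and 1, and Nfe2l2 in 3 and 2. Unfolded protein response genes stood at 16 ± 1 and 15.3 ± 6.43 of 23 (exact permutation p = 0.8, n = 3 each), where TNBS 2 had 8, TNBS 1 and TNBS 3 had 20 and 18 and the normal libraries 15 to 17, with Atf4, Edem1 and Syvn1 in 0 normal and 2 TNBS libraries and the chaperone Calr in 3 and 1. Autophagy and Crohn's disease susceptibility genes stood at 22.3 ± 2.08 and 21.7 ± 3.21 of 25 (exact permutation p = 0.5, n = 3 each), with 24, 18 and 23 in the TNBS libraries. Tnfsf15, a TNF family cytokine gene linked to Crohn's disease, had a peak in 3 of 3 normal and 0 of 3 TNBS libraries, from 63727062 to 63730043 on chromosome 4 in normal 1. Ptpn2 had one in 1 normal and 3 TNBS libraries, and Il10rb and Xbp1 in all but TNBS 2.

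**Figure D3:**
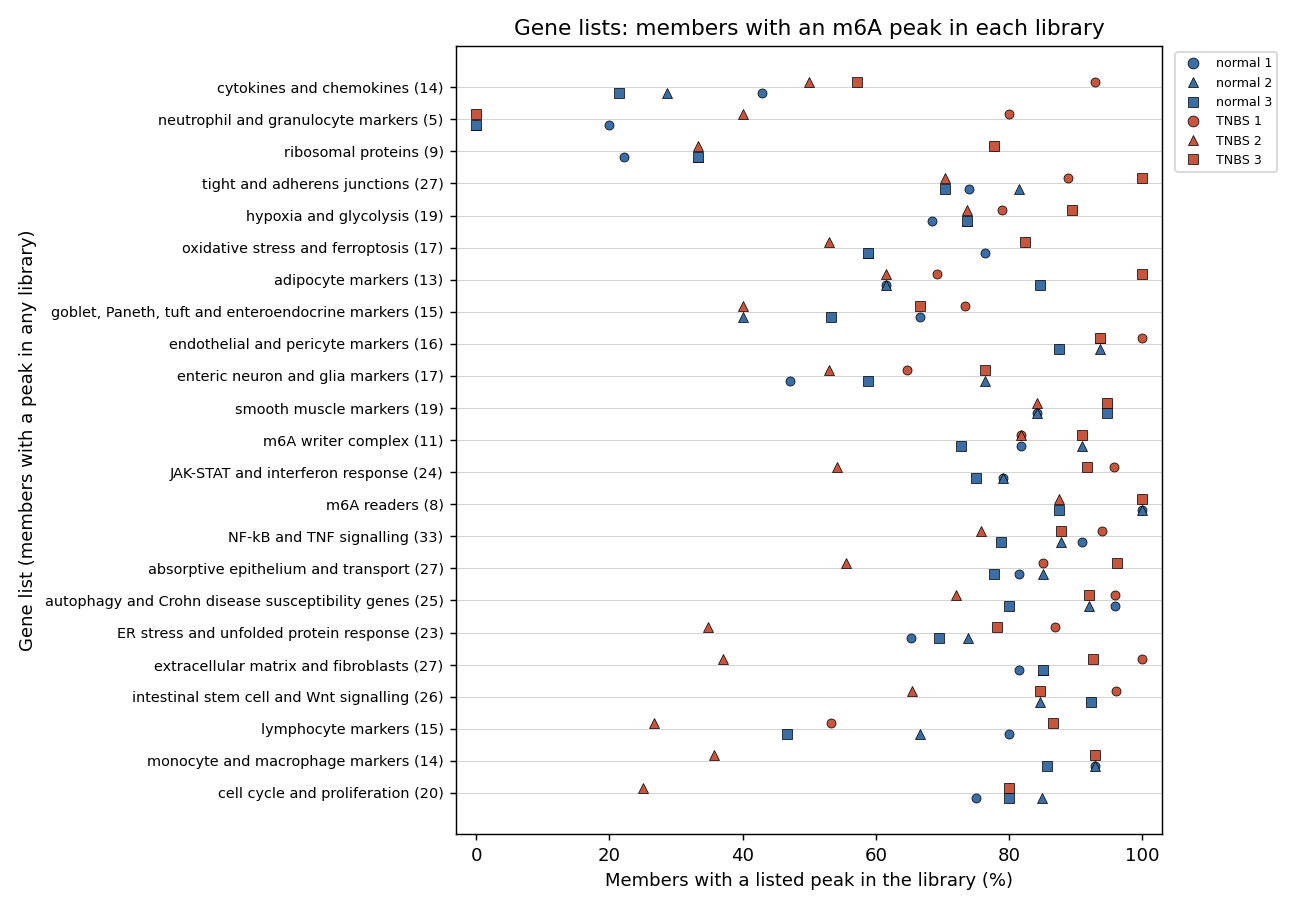
Share of each gene list's members with a listed peak in each library, in percent of the members with a peak in any of the 6 libraries (their number is in brackets), with 1 symbol per mouse, normal in blue and TNBS in red, and equal values drawn over each other. Cytokines and chemokines are the list in which all 3 TNBS libraries lie above all 3 normal ones, with 13, 7 and 8 members against 6, 4 and 3.

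None of the 23 tested lists was over-represented among the restricted genes after adjustment: 0 of 46 Fisher's exact tests had an adjusted p under 0.05, and 1 had an unadjusted p under 0.05. That was the ribosomal protein list, with Rplp1 and Rps9 among the TNBS-restricted genes (2 of 9 members, Fisher's exact p = 0.00338, adjusted p = 0.156), and it passed, with 5 of 9 members, without TNBS 2 (adjusted p = 0.00115). Cytokines and chemokines were the list whose member counts separated the groups fully, where chance gives 10% of lists, 2.3 of 23. Relative to all genes the exact permutation p was 0.1 for 4 lists, the cytokine, junction, ribosomal and macrophage lists, and 0.575 after Benjamini-Hochberg adjustment. Among random lists matched on the number of libraries, the mean difference of the cytokine list lay at percentile 99.9, that of the junction list at 99.7, of the ribosomal list at 92.1 and of the macrophage list at 18.9, which describes these genes and not the spread between mice.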

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

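The tests on the sex chromosomes and on peaks outside the mRNA lists were chosen after the values had been seen, and those on the restricted genes were fixed beforehand. By its rule set beforehand the test on calls near the threshold would have argued against that explanation; the further condition that most restricted genes in each direction pass a caller's p of 1e-10 was added after the values had been seen, and left it open.

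The caller gave a false discovery rate of 100% to 66.6% of the listed peaks in TNBS 1, 100% in TNBS 2 and 99.99% in TNBS 3, above the highest normal library, at 37.8%.

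The caller numbers every peak it makes, and the highest number was 256774 in TNBS 2 and 102214 in TNBS 3, above 89218 in the highest normal library. The mRNA list held 4.27% of the numbered peaks in TNBS 2, below the 15.7% to 30.1% of the normal libraries, while TNBS 3 at 18.9% and TNBS 1 at 23.5% lay inside that range, so a low share was not a feature of the TNBS libraries as a group. Over the 19 autosomes of each library, the numbered peaks outside the lists correlated more with the length of the chromosome that peaks span than with its number of protein-coding genes, by at least 0.0773 in r, with r of 0.988 against 0.665 in TNBS 2. Chromosomes are not independent replicates, but the pattern is consistent with background that follows genomic length, for which genomic DNA or unspliced RNA in the libraries is a candidate source. Other transcript classes that the mRNA lists leave out were not separated from it.

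The labels say that the mice were male, yet TNBS 1 and TNBS 3 listed no peak in the male-specific part of the Y chromosome, and their numbering leaves room for at most 70 and 67 Y peaks, against at least 598 to 1753 in normal libraries and 5472 in TNBS 2. Their numbered X peaks per 100 autosomal peaks were 4.99 and 5.00, above the highest normal library at 3.10 and TNBS 2 at 3.06. Lower detection is argued against by the autosomal regions called in the other 4 libraries, of which TNBS 1 found 97.7% and TNBS 3 96.6%, while each found 0 of 5 such Y regions (exact 95% confidence limit 52.2%), and TNBS treatment itself by the 19 Y peaks of TNBS 2. A candidate explanation that stays open is nucleic acid from animals with 2 X and no Y chromosome. The X figure was 1.71 times that of the other 4 libraries. The X share of the mRNA lists was 0.893 times theirs, which cannot decide the question, since peaks in mRNA need not follow the number of X chromosomes. Whether mice of the other sex were used or samples were exchanged was not tested, and any effect of sex is then mixed with colitis in these libraries.

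The 235 genes restricted to a group exceeded the 121 of the highest other split, and the 664 regions exceeded 435, each in 1 of 10 splits, which are too few to reach a share under 0.05. Calls near the caller's threshold stay open: the strongest peaks of these genes had a mean percentile of 38.2 within their lists, 9.16 above other genes called in exactly 3 libraries (29.0, one-sided permutation p = 1e-05, the smallest the permutations can give) but below the 70.6 of genes called in all 6, and at a caller's p of 1e-10 or less 40 of the 115 TNBS and 67 of the 120 normal genes stayed restricted, so ranking above those other genes does not show that most lay far from the threshold. At equal list length an excess over other splits was also present, the outcome that the rule set beforehand counted against unequal list length. With the same number of peaks from each list 347 genes were restricted, where the highest other split gave 64. Most of these were different genes, with 45 of 137 and 44 of 210 shared with the full lists. For the 115 and 120 genes of the full lists themselves, unequal list length therefore stays open. Different transcript abundance, the sex chromosome pattern of TNBS 1 and TNBS 3, and a change of m6A with colitis also stay open and were not tested. The same holds for less reliable calls in the TNBS lists, whose caller's false discovery rates were higher. Every gene restricted to TNBS needs a peak in TNBS 2, where 100% of the listed peaks had a rate of 100%.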

How the results depend on the processing

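The runs with TNBS 2 as the sole TNBS library and without chromosomes X and Y were added after the data had been seen; the rest were planned.

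The differences in peaks (735) and genes (-69.0) per library had no settled direction. Leaving out each library in turn gave -739.8 to 3417 peaks and -529 to 798.5 genes. Since no exact p can go under 0.1 in this design, the p-values say nothing about stability. At equal list length the peak count is fixed and has no value. The difference in Jaccard index ran from -0.00485 to 0.0994 over the libraries left out. It was 0.0413 at a caller's p of 1e-10 or less, 0.0423 at a fold enrichment of at least 4 and 0.0590 at equal list length. With an overlap of at least 50% of the shorter peak, the index counted shared regions in place of bases, and the difference was 0.0553. Pairing by replicate number leaves the index unchanged by construction.

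By construction, looser definitions raised the restricted counts. A peak in at least 2 of 3 libraries against 0 of 3 gave 636 TNBS and 314 normal genes and 2340 and 1147 regions, and 3 of 3 against at most 1 of 3 gave 257 and 463 genes and 558 and 1212 regions. Leaving out 1 library gave 151 to 537 TNBS and 145 to 347 normal genes and 316 to 2102 and 475 to 930 regions. The same number of peaks from each list gave 210 normal genes, and a caller's p of 1e-10 or less gave 168 TNBS regions; the cause of both was not tested. With TNBS 2 as the sole TNBS library, the fewer libraries gave 510 TNBS and 1762 normal genes and 1243 and 3678 regions. Without chromosomes X and Y 110 genes were restricted in each direction.

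The number of gene lists past the threshold was 0 to 1 over the libraries left out and 1 for at least 2 of 3 against 0 of 3, each time ribosomal proteins among the TNBS-restricted genes (5 of 9 members: Rplp0, Rplp1, Rps3, Rps9 and Rps19; Fisher's exact test, adjusted p = 0.00115 without TNBS 2 and 0.00240). It was 0 in the other settings. Of 227 values of single lists under an alternative, 221 moved by no more than the larger group SD and 6 by more. The 227 include the pairing by replicate number, which repeats the main values by construction, and TNBS 2 widens the SD of many lists. The cytokine list, the one with full separation, kept its sign, with a difference in share of 0.339 to 0.448. Whether the separation itself held was not followed. Of the genes restricted to a group, 40 of 115 (TNBS) and 67 of 120 (normal) stayed so at a caller's p of 1e-10 or less, 107 and 112 at a fold enrichment of at least 4, and 45 and 44 at equal list length. The 24 named ones were mostly chosen for strong peaks and so favoured by stricter filters. Of these, 21 stayed at 3 of 3 against 0 of 3 under all of these filters, and the exceptions were Ccl5, Rplp1 and Tjp3. Single genes were not followed under gene assignment by overlap. That setting matters for Tor2a, Hist1h2ad, Ttc16 and Tmem132a, which overlapped peaks that the other group's lists gave to neighbouring genes.

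The replicate numbers did not pair the mice: deviations of same-numbered libraries correlated at 0.0319, -0.0537 and -0.0356 across genes. With the numbers as a block, the mean difference was 735 peaks (exact sign-flip p = 1) and -69.0 genes (exact sign-flip p = 1), and the restricted counts were the same by definition. The smallest sign-flip p of 3 pairs is 0.25, so the block could not have changed a call. The share of peaks in the 3' UTR and at the m6A sequence motif was planned and not run, since transcript parts and sequence were not used here. Read depth was not given, so its effect on which peaks were called is unknown.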

Other observations

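The gene families below were picked from the symbols after the data had been seen, and so were the pathway tests.

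Of 317 genes whose symbol starts with Zfp and that had a peak in any library, 295, 290 and 268 had a peak in the normal libraries and 260, 203 and 254 in the TNBS libraries. Among them, 11 had a peak in every normal and no TNBS library and 0 the reverse (two-sided Fisher's exact test, adjusted p = 0.00272 for the normal direction over 6 tests and 0.142 for the other). These tests cover only the 3 families picked and ran on the genes that led to the choice, so their p-values describe these lists and show no difference between groups. Over 10 alternatives the number was 10 to 20 and the unadjusted Fisher's exact p ran from 3.72e-05 to 0.0119, with the highest without TNBS 1. The 10 include the pairing by replicate number, which repeats the main values by construction. Relative to all genes the exact permutation p between mice was 0.1, the smallest possible. Subunits of the mitochondrial respiratory complexes had a peak in 34, 33 and 32 of 52 genes in the normal and 46, 29 and 48 in the TNBS libraries, with 2 TNBS-restricted and 0 normal-restricted members (Fisher's exact test, adjusted p = 0.142 and 1; exact permutation p between mice 0.1 relative to all genes). Solute carriers had 5 TNBS-restricted and 3 normal-restricted members of 226 (Fisher's exact test, adjusted p = 0.142 and 0.612).

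Of 538 Fisher's exact tests on the pathways that the authors' lists name for each gene, 0 had an adjusted p under 0.05 and 13 an unadjusted p under 0.05.

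On the male-specific part of the Y chromosome, Rbmy, known for its expression in male germ cells, had a peak in all 3 normal libraries and TNBS 2, and the demethylase gene Kdm5d in normal 1, normal 2 and TNBS 2. Ddx3y and Uty had one in TNBS 2 alone. These genes were chosen after their values were seen.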
